A study of Caenorhabditis elegans with 12 samples.

How the data were processed

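The data are RNA sequencing counts from 12 pools of whole Caenorhabditis elegans of strain AM140, which carries a transgene of 35 glutamines fused to yellow fluorescent protein (YFP) under the unc-54 promoter, a promoter active in body wall muscle. Per the labels, synchronized worms grew at 20 °C on EV bacteria (in RNAi work usually the empty vector control) or on bacteria for YFP RNAi, moved to fresh plates each day to take away offspring, and a part of each group met isoflurane on day 5 of adulthood. All were collected 3 h after that treatment. The labels state neither the dose and length of the exposure nor how the unexposed worms were handled. Libraries came from poly(A) RNA with a stranded kit, per the labels.

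The authors deposited 1 table with raw read counts per gene and library and, beside them, a signal that the file headers call DESeq2 normalized counts. Per the submitters' processing notes, cutadapt 2.10, TopHat2 2.1.1, HTSeq 2.01 and DESeq2 1.36.0 were used with genome build WBcel235. The strand setting of the counting is not given in the sources used here, so reads of a gene and of one on its opposite strand may not be told apart. The table has 46934 lines, of which 22416 carry counts. The deposited signal was checked to be the count divided by 1 size factor per library (0.849 to 1.21), given for the 18045 genes with at least 10 reads in total. It was not used further, and all tests below rest on the raw counts. Of the 22416 gene IDs, 22406 are in the Ensembl annotation of WBcel235, from which coordinates were taken. A spreadsheet had turned 11 gene names into dates, and these were restored by gene ID. Library totals were 21831518 to 31268121 reads, and the median SE of a log2 fold change was 0.193 (0.272 for the interaction). For a gene with 0 reads in a group, the fold is a bound against 3 counts over that group, which covers counting error only.

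Groups and replicate numbers follow the labels: EV, YFP RNAi, EV with isoflurane and YFP RNAi with isoflurane, with 3 libraries each. Counts were fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersions, TMM normalization and filterByExpr (least count 10), all 12 libraries in 1 fit with 4 groups. This left 14326 genes. The biological coefficient of variation was 0.179. The contrasts were isoflurane against none on each kind of bacteria, YFP RNAi against EV without and with isoflurane, and the interaction, which is the response on EV bacteria minus the response on YFP RNAi bacteria. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05. CPM are counts scaled to library size (edgeR cpm) after TMM, and the error of a log2 fold change is the standard error (SE) from the F statistic. Adjusted p values are from edgeR unless another tool is named.

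The tests, 45 gene lists and the rule for named genes were fixed before the data were examined. The rule takes unc-54 first, then the 10 largest rises and 10 largest falls of each test among named genes with an average of at least 1 log2 CPM and no overlap between groups, the 2 largest of any name, up to 4 members of each list with the smallest p, and 16 stress and mitochondrial genes in every case. Where fewer than 5 genes passed, the 5 with the smallest p are given. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 225 tests (45 lists, 5 contrasts). An estimated correlation was used beside it. The fry test, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, was also run. The overlap of the isoflurane responses was tested with a one-sided Fisher exact test per direction. These comparisons share no libraries, but both take the spread of a gene from the 1 fit of all 12 libraries, so their calls are not independent.

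The labels give replicate numbers 1 to 3 in every group but do not say what they stand for. Deviations from the group means correlated between libraries of the same number at 0.38 to 0.46 for isoflurane on EV bacteria, at 0.28 to 0.57 for isoflurane on YFP RNAi bacteria and at 0.23 to 0.27 for YFP RNAi with isoflurane, so the numbers were taken to pair the libraries there, as a pattern of the data and not a statement of the labels. Between EV and YFP RNAi without isoflurane they were 0.03 to 0.44, and the numbers were not taken to pair these. The replicate block used below shares its terms over all 4 groups, so it joins these libraries too. A block for each number within 1 kind of bacteria was not fitted, and the main fit holds no pairing. No pair of libraries was a duplicate of another: the lowest chi-square per degree of freedom over all pairs of libraries was 6.26. This was the value of EV and YFP RNAi replicate 3, below the lowest between libraries of 1 group (12.4). For EV and YFP RNAi replicate 2 it was 9.13.

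Alternatives were DESeq2 size factors within edgeR, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, a 2-fold size threshold, only the 6 libraries compared, and leaving out each of the 12 libraries in turn. Leaving out both EV libraries of replicate number 2 was added after seeing the data. On simulated data with 200 changed genes, edgeR recovered 59.7% of the genes changed 2-fold and 31.3% of those changed 1.5-fold for isoflurane on EV bacteria, out of 14124 tested. At 4-fold it recovered 86.4% there. For isoflurane on YFP RNAi bacteria it recovered 25.4%, 52.2% and 83.3% at 1.5-fold, 2-fold and 4-fold, out of 14134 tested. For the interaction it recovered 41.8% at 2-fold, 11.9% at 1.5-fold and 63.6% at 4-fold, out of 14124 tested. For YFP RNAi without isoflurane it recovered 25.4%, 49.3% and 84.8% at these folds (14134 tested), and with isoflurane 32.8%, 62.7% and 84.8% (14124 tested). Unchanged genes called were 11, 5, 1, 6 and 6 in this order of tests. By DESeq2 they were 31, 26, 26, 30 and 30. For YFP RNAi, DESeq2 called 12 and 15 genes in the real data. With 200 changed genes the adjusted cutoff is looser, so the simulated counts do not measure false calls among these. The simulated libraries were drawn independently, without the pairing described above. Each gene mapped to a family of near-identical copies is uncertain where reads could be split between copies, among them hsp-16, F44E5.4 and F44E5.5, ugt-33 to ugt-35, and the msp and clec genes.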

Results

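Pools of whole AM140 worms were sequenced in 4 groups of 3 libraries, which cross 2 kinds of bacteria (EV or YFP RNAi) with isoflurane or none. YFP RNAi targets the polyglutamine-YFP transgene of this strain, but the load of the aggregating protein was not measured here. Libraries held 21831518 to 31268121 counted reads, and their 10 most abundant genes took 7.38% to 11% of them. The first principal component, with 50.2% of the variance, parted all 6 isoflurane libraries from all 6 controls. On the second (14.1%), EV and YFP RNAi libraries lay interleaved. There all libraries of replicate number 3 had positive values and all of number 2 negative ones. Those of number 1 were positive on EV and negative on YFP RNAi bacteria.

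**Figure D1:**
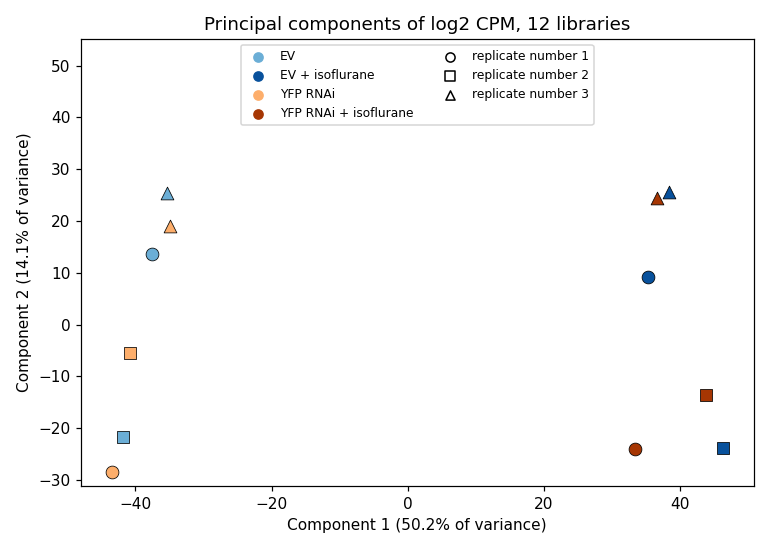
Principal components of log2 CPM over the 14326 genes tested, with 1 point per library, colour for the group and shape for the replicate number. Component 1 (50.2% of the variance) separates isoflurane libraries from controls, and EV and YFP RNAi libraries lie interleaved on component 2 (14.1%).

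The transgene itself has no line of its own in the count table, so its knockdown was not measured here. The gene unc-54 (WBGene00006789, chromosome I, 14855901 to 14863482, WBcel235), a body wall muscle myosin heavy chain whose promoter drives the transgene, varied more between replicates than between groups. On EV bacteria it stood at 699, 1580 and 495 CPM in replicates 1 to 3, and at 670, 1609 and 540 CPM with isoflurane. On YFP RNAi bacteria it stood at 1021, 1068 and 540 CPM, and at 947, 1151 and 464 CPM with isoflurane. None of the 5 tests called it, and its isoflurane response on EV bacteria had a log2 fold change of 0.02 ± 0.54 (SE; edgeR adjusted p = 0.99).

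Isoflurane on EV bacteria was followed by large rises of genes for the metabolism of foreign compounds. The cytochrome P450 gene cyp-34A10 (WBGene00015045, chromosome V, 3970702 to 3972991, WBcel235) rose from 3.23 ± 1.6 CPM to 1191 ± 91 CPM (SD, n = 3), a log2 fold change of 8.55 ± 0.77 (edgeR adjusted p = 4.6e-05). UDP-glucuronosyltransferases, which attach sugar acids to such compounds, rose with it: ugt-34 by 8.51 ± 0.39 and ugt-33 by 8.01 ± 0.67 on the log2 scale. The gene ugt-35 had 0 reads in the EV libraries and was at least 94.5-fold higher with isoflurane. Further large log2 rises were those of the uncharacterised F38C2.1 (9.71 ± 0.66), the C-type lectins clec-210 (7.02 ± 0.31), clec-206 (6.96 ± 0.39) and clec-174 (5.96 ± 0.80), the glucosylceramidase gene gba-2 (6.73 ± 0.64), cyp-14A2 (6.46 ± 0.37) and the insulin-like peptide ins-11 (6.26 ± 0.64). The largest falls of named genes were those of pud-1.2 (-4.73 ± 0.46), scl-20 (-4.27 ± 0.57), gpdh-1 (-3.73 ± 0.41), clec-4 (-3.71 ± 0.65), sdz-24 (-3.58 ± 0.37), dhs-26 (-3.49 ± 0.39), pcp-2 (-3.36 ± 0.31), cyp-29A4 (-3.32 ± 0.35), dod-3 (-3.31 ± 0.55) and pud-3 (-3.28 ± 0.64). In all, edgeR called 1026 of 14326 genes, 646 up and 380 down, and 703 of them changed at least 2-fold. Between the groups 2922 genes did not overlap, 20.4% of those tested against 10% by chance. With the replicate numbers as a block the count was 1389. DESeq2 gave no adjusted p for cyp-34A10, for which its log2 fold change was 8.53.

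**Figure D2:**
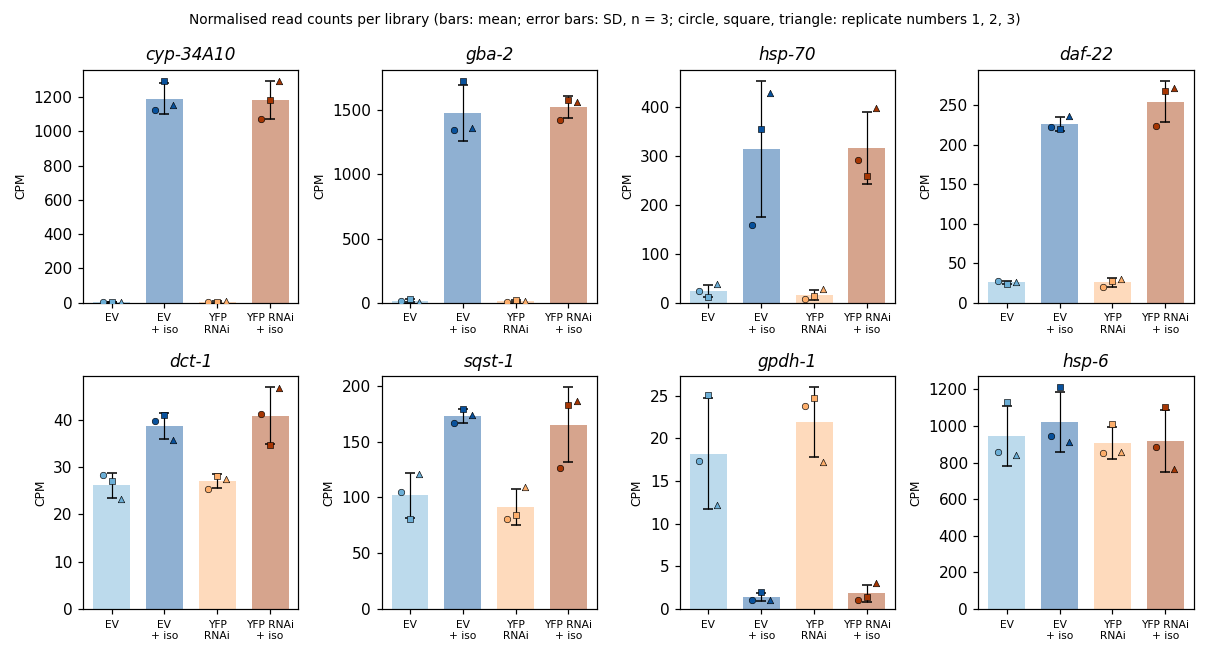
CPM of 8 genes per library (bars: mean; error bars: SD, n = 3; points: libraries by replicate number). On both kinds of bacteria, cyp-34A10, gba-2, hsp-70, daf-22, dct-1 and sqst-1 were higher and gpdh-1 lower with isoflurane, while hsp-6 passed neither test.

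Of 65 measured cytochrome P450 genes on EV bacteria, 25 rose, 8 fell and 32 did not pass (28 up and 14 down adjusted over the list alone). Members with the smallest p were cyp-29A3 (log2 fold change 4.92 ± 0.20), cyp-29A2 (4.06 ± 0.17), cyp-25A3 (4.79 ± 0.25) and cyp-14A2. The camera test of the list gave an adjusted p = 4.4e-14, and an adjusted p = 0.456 with an estimated correlation. Of 64 UDP-glucuronosyltransferase genes, 27 rose, 8 fell and 29 did not pass (29 up and 15 down adjusted over the list alone), with ugt-8 at 5.11 ± 0.17 and ugt-52 at 3.98 ± 0.26. Their camera adjusted p was 1.2e-17, with an adjusted p = 0.232 with an estimated correlation. Fry, which asks whether members move on balance 1 way, gave adjusted p = 0.00457 for the cyp list and 0.00143 for the ugt list. Glutathione S-transferases went both ways: 5 of 35 rose, 7 fell and 23 did not pass, with gst-5 (3.99 ± 0.35) and gst-6 (1.55 ± 0.18) higher and gst-26 (-1.93 ± 0.23) and gst-4 (-1.74 ± 0.26), a widely used SKN-1 reporter gene, lower. Of 30 P-glycoprotein and ABC transporter genes, 4 rose and 3 fell, among them pgp-14 (2.60 ± 0.17), haf-7 (1.14 ± 0.15) and haf-9 (-1.58 ± 0.18). For neither list did camera pass (adjusted p = 0.928 and 0.546).

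Cytosolic heat shock genes rose on EV bacteria. The inducible chaperone hsp-70 (WBGene00002026, chromosome I, 9320325 to 9322519, WBcel235) went from 24.2 ± 13 CPM to 314 ± 140 CPM (SD, n = 3), with a log2 fold change of 3.69 ± 0.56 (edgeR adjusted p = 0.00178), and stayed called without any 1 library (highest adjusted p = 0.0117). The small heat shock gene hsp-16.2 rose by 3.91 ± 0.85 on the log2 scale (adjusted p = 0.0167), a call that ended without EV replicate 1 (adjusted p = 0.0804) or EV replicate 2 (adjusted p = 0.0515), or with no filter on low counts (adjusted p = 0.0651; 2.77e-04 to 0.118 over all alternatives). Of 27 members 7 rose and 20 did not pass (13 up adjusted over the list alone), and 24 had a log2 fold change above 0. Without 1 library the 7 became 3 (EV replicate 1 or EV replicate 2) or 4 (EV with isoflurane, replicate 2 or 3). With no filter on low counts 4 were called, with the replicate block 10 and by DESeq2 12. The camera test gave an adjusted p = 1.6e-05, with an adjusted p = 0.681 with an estimated correlation, and fry gave an adjusted p = 0.0161. Body wall muscle and sperm marker RNA was higher in both EV libraries of replicate number 2 than in the other EV libraries, and without both of these 2 heat shock members were called and the log2 fold change of hsp-16.2 was 3.08 (adjusted p = 0.118).

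Few organelle stress genes were called on EV bacteria. The mitochondrial chaperones hsp-6 (log2 fold change 0.12 ± 0.16, edgeR adjusted p = 0.84) and hsp-60 (0.04 ± 0.09, adjusted p = 0.90) did not pass on EV bacteria. Of 20 mitochondrial unfolded protein response genes, edgeR called 0, with 2 at an unadjusted p under 0.05 and 1 called by DESeq2. The endoplasmic reticulum chaperone hsp-4 had a log2 fold change of 0.43 ± 0.15 (adjusted p = 0.12). It went from 555, 442 and 585 CPM to 682, 667 and 775 CPM in replicates 1 to 3. The groups thus did not overlap, as for 20.4% of the genes tested. In the endoplasmic reticulum list of 27, the stress transcription factor atf-4 rose by 1.53 ± 0.14 (adjusted p = 1.9e-05). It was the only member edgeR called (DESeq2 called 2, both higher), and 26 did not pass. Without EV with isoflurane replicate 2 the list had 2 calls.

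Receptors for selective autophagy rose by less than 2-fold on EV bacteria. The mitophagy receptor dct-1 (WBGene00015776, chromosome X, 7954354 to 7956225, WBcel235) went from 26.1 ± 2.7 CPM to 38.7 ± 2.8 CPM (SD, n = 3), with a log2 fold change of 0.57 ± 0.12 (edgeR adjusted p = 0.00841; 0.0626 without both EV libraries of number 2, and 1.24e-04 to 0.0626 over all alternatives). The p62 homolog sqst-1 (WBGene00011737, chromosome IV, 12034282 to 12036891, WBcel235) rose by 0.76 ± 0.18 (adjusted p = 0.0199). Its call ended without EV replicate 1 (adjusted p = 0.0685), EV replicate 2 (0.0804), or EV with isoflurane replicate 1 (0.0505), 2 (0.0677) or 3 (0.0592), and without both EV libraries of number 2 the adjusted p was 0.180 (8.59e-04 to 0.180 over all alternatives). The beclin gene bec-1 rose by 0.57 ± 0.12. Of 26 mitophagy and mitochondrial dynamics genes 3 rose and 23 did not pass (4 up adjusted over the list alone, 4 up by DESeq2); the third riser, mul-1 (2.93 ± 0.30), encodes a mucin-like protein. The camera test of this list did not pass (adjusted p = 0.133), while fry did (adjusted p = 0.0304). Values of others that did not pass were -0.13 ± 0.08 for the kinase pink-1, 0.05 ± 0.06 for pdr-1, the worm parkin, 0.16 ± 0.12 for lgg-1, the autophagosome marker, and 0.18 ± 0.13 for hlh-30, the worm TFEB. Of 34 autophagy genes 2 rose (sqst-1 and bec-1), and without any 1 of the 5 libraries that ended the sqst-1 call 1 did. Of 39 lysosome genes 1 rose and 2 fell, among them the proton pump subunit vha-6 (-1.13 ± 0.16). All 33 proteasome genes had a log2 fold change above 0 (median 0.17), but edgeR called 0 of them, with 13 at an unadjusted p under 0.05 and 2 called by DESeq2. Their camera adjusted p was 0.00288, with an adjusted p = 0.985 with an estimated correlation; this call ended without EV replicate 2 (0.0846) or EV with isoflurane replicate 2 (0.105), and fry did not pass (adjusted p = 0.426).

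None of the respiratory chain genes measured was called on EV bacteria. The complex I list held 30 nuclear genes, of which 13 were found under their listed names and 12 were measured. Of 12 complex I genes encoded in the nucleus edgeR called 0 (1 at an unadjusted p under 0.05, DESeq2 0), with gas-1, a complex I subunit whose mutants are hypersensitive to volatile anaesthetics, at -0.19 ± 0.07 (adjusted p = 0.14). Of 33 genes of complexes II to V it called 0 (1 unadjusted, DESeq2 0), with isp-1 at 0.05 ± 0.08 (adjusted p = 0.87), and of 12 mitochondrial genome genes 0 (0 unadjusted, DESeq2 0). Of 36 genes for anaesthetic sensitivity and presynaptic release edgeR called 0, with 10 at an unadjusted p under 0.05 and 3 called by DESeq2. Lowest in p were egl-19 (-0.57 ± 0.17), snb-1 (0.23 ± 0.07) and the potassium channel slo-1 (-0.49 ± 0.15, adjusted p = 0.087).

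Of the fatty acid oxidation and metal response lists, some genes changed on EV bacteria. The last thiolase of ascaroside shortening, daf-22, rose by 3.12 ± 0.14 on the log2 scale, together with acox-1.1 (2.35 ± 0.14) and dhs-28 (1.49 ± 0.15), enzymes of the same peroxisomal cycle, while acox-1.2 (-1.50 ± 0.14) fell. The mitochondrial acyl-CoA synthetase acs-2 fell by 2.53 ± 0.64 (edgeR adjusted p = 0.0361), a call that ended without EV replicate 3 (0.111), EV with isoflurane replicate 1 (0.122), 2 (0.0755) or 3 (0.0759), or YFP RNAi with isoflurane replicate 2 (0.0556) or 3 (0.0587). With no filter on low counts its adjusted p was 0.111, and without both EV libraries of number 2 it was 0.0959 (0.00282 to 0.122 over all alternatives). Of 31 fatty acid oxidation genes 8 rose, 2 fell and 21 did not pass (9 up and 3 down adjusted over the list alone), with a median log2 fold change of 0.00 and a mean of 0.15; camera gave an adjusted p = 0.00164, with an adjusted p = 0.456 with an estimated correlation, and fry an adjusted p = 0.00676. Of 13 metal response genes 6 rose and 1 fell, with cdr-1 (3.35 ± 0.22), cdr-4 (2.22 ± 0.34), the zinc sensor hizr-1 (1.33 ± 0.25) and the metallothionein mtl-1 (1.74 ± 0.31) higher; camera gave an adjusted p = 0.00117, with an adjusted p = 0.681 with an estimated correlation, and fry an adjusted p = 0.0211. Of 32 oxidative stress genes 5 rose and 3 fell, with sod-1 (0.85 ± 0.12) and dhs-8 (2.74 ± 0.22) higher. The mitochondrial superoxide dismutase sod-3, a DAF-16 target, had a value of 0.50 ± 0.40 (adjusted p = 0.65). Of 21 DAF-16 type targets 3 rose and 1 fell.

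On EV bacteria 1 of 6 vitellogenins, 6 of 107 collagens and 2 of 12 osmotic stress genes fell. The yolk protein gene vit-1 fell by 1.91 ± 0.26 on the log2 scale (edgeR adjusted p = 5.3e-04), the only 1 of 6 vitellogenins that edgeR called (2 without EV replicate 3, and 2 by DESeq2), and all 6 had values below 0 (median -0.71; camera adjusted p = 0.00470, with an adjusted p = 0.985 with an estimated correlation). Of 107 collagens edgeR called 6, all lower, among them col-98 (-2.23 ± 0.37), and DESeq2 12 lower and 1 higher; 4 fell adjusted over the list alone. The 6 became 3 without EV replicate 2, 2 without EV with isoflurane replicate 1 or 3, and 12 without EV with isoflurane replicate 2. Camera gave an adjusted p = 2.7e-04 for the collagens and 0.0322 for 25 hypodermis and cuticle genes, of which 3 fell (1 without EV with isoflurane replicate 3); both lists had an adjusted p = 0.985 with an estimated correlation. Fry passed none of these 3 lists (adjusted p = 0.369 for the vitellogenins, 0.560 for the collagens and 0.426 for the hypodermis). The camera call of the hypodermis list ended without EV replicate 1 (0.0800) or 2 (0.0531), or EV with isoflurane replicate 3 (0.136). The glycerol synthesis gene gpdh-1 and the inositol transporter gene hmit-1.1 (-1.96 ± 0.35) fell, and 1 of 12 osmotic stress genes rose; the camera test of that list did not pass (adjusted p = 0.271). Of 22 hypoxia and sulfide genes edgeR called 3, all lower, fmo-2 (-2.91 ± 0.51), sqrd-1 (-0.95 ± 0.12) and acs-2, and DESeq2 4 lower and 2 higher; without YFP RNAi with isoflurane replicate 1 the list had 5 calls.

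On YFP RNAi bacteria the largest rises of named genes with isoflurane were those of ugt-34 (log2 fold change 8.20 ± 0.37), cyp-34A10 (7.80 ± 0.74, 5.2 ± 6.0 CPM to 1183 ± 110 CPM, SD, n = 3), ugt-33 (7.39 ± 0.64), clec-206 (7.06 ± 0.39), clec-174 (6.72 ± 0.86), clec-210 (6.65 ± 0.30), gba-2 (6.63 ± 0.64), cyp-14A2 (6.59 ± 0.37), ugt-35 (6.4 ± 0.47) and cyp-35A5 (5.93 ± 0.41), and F38C2.1 rose by 8.16 ± 0.57. DESeq2 gave no adjusted p for cyp-34A10 here either (log2 fold change 7.81). The largest falls were those of pud-1.2 (-4.37 ± 0.44), scl-20 (-3.76 ± 0.55), gpdh-1 (-3.56 ± 0.39), cyp-29A4 (-3.49 ± 0.36), dhs-26 (-3.47 ± 0.39), ugt-43 (-3.25 ± 0.62), clec-4 (-3.09 ± 0.62), pcp-2 (-3.08 ± 0.30), the ammonium transporter gene amt-4 (-3.08 ± 0.41) and nas-3 (-2.97 ± 0.34). In all, edgeR called 1071 of 14326 genes, 791 up and 280 down, and 757 of them changed at least 2-fold. Groups did not overlap for 2982 genes, 20.8% against 10% by chance, and with the replicate numbers as a block the count was 1470.

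Heat shock genes rose on YFP RNAi bacteria as well. The log2 fold change was 4.27 ± 0.58 for hsp-70 (edgeR adjusted p = 7.8e-04; 16.3 ± 10 CPM to 316 ± 73 CPM, SD, n = 3) and 2.88 ± 0.50 for F44E5.5. It was 4.33 ± 0.87 for hsp-16.2 (adjusted p = 0.0104), whose call ended without YFP RNAi replicate 1 (0.0535) or replicate 2 (0.0519). Of 27 members 10 rose and 17 did not pass (13 up adjusted over the list alone), which became 6 without YFP RNAi replicate 1 and 5 without YFP RNAi replicate 2. With no filter on low counts 8 were called, with the replicate block 11 and by DESeq2 12. Camera gave an adjusted p = 3.7e-06, with an adjusted p = 0.675 with an estimated correlation, and fry an adjusted p = 0.00779. The chaperones of the other compartments did not pass: hsp-6 stood at 0.02 ± 0.16, hsp-60 at -0.03 ± 0.09 and hsp-4 at 0.44 ± 0.15 (adjusted p = 0.11), while atf-4 rose by 1.52 ± 0.14. Here hsp-4 went from 468, 473 and 627 CPM to 663, 648 and 817 CPM in replicates 1 to 3, again without overlap (20.8% of genes tested). Of 20 mitochondrial unfolded protein response genes edgeR called 0, with 1 at an unadjusted p under 0.05 and 0 by DESeq2.

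In the mitophagy and mitochondrial dynamics list on YFP RNAi bacteria, dct-1 rose by 0.60 ± 0.12 on the log2 scale (edgeR adjusted p = 0.00572). The gene sqst-1 rose by 0.86 ± 0.18 (adjusted p = 0.00982), and mul-1, which encodes a mucin-like protein, by 3.09 ± 0.30. Of 26 members 23 did not pass. Neither camera (adjusted p = 0.268) nor fry passed the list here. Without YFP RNAi replicate 1 or 2 the adjusted p of sqst-1 was 0.0529 or 0.0535. That of bec-1 (0.54 ± 0.12) was then 0.0699 or 0.0694, and 0.0536 without YFP RNAi with isoflurane replicate 3. So 2 of 34 autophagy genes rose, but 0 without YFP RNAi replicate 1 or 2 and 1 without YFP RNAi with isoflurane replicate 3. The values of pink-1 (-0.11 ± 0.08), pdr-1 (-0.03 ± 0.06), lgg-1 (0.26 ± 0.12), hlh-30 (0.15 ± 0.13), gas-1 (-0.15 ± 0.07), isp-1 (-0.03 ± 0.08) and sod-3 (1.02 ± 0.40) did not pass. All 33 proteasome genes again lay above 0 (median 0.17), with 0 called by edgeR, 9 at an unadjusted p under 0.05 and 0 called by DESeq2. Their camera adjusted p was 0.0124, with an adjusted p = 0.985 with an estimated correlation and 0.0507 with the replicate block; this call ended without YFP RNAi replicate 2 (0.107) or YFP RNAi with isoflurane replicate 1 (0.188) or 2 (0.0567), and fry did not pass (adjusted p = 0.483).

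Cytochrome P450 and UDP-glucuronosyltransferase genes changed on YFP RNAi bacteria in numbers similar to those on EV bacteria. Of 65 cytochrome P450 genes 26 rose and 6 fell (31 and 10 adjusted over the list alone), and of 64 UDP-glucuronosyltransferase genes 28 rose and 5 fell (33 and 9). The examples cyp-29A3 (log2 fold change 5.27 ± 0.20), cyp-29A2 (4.14 ± 0.17), ugt-8 (5.12 ± 0.17) and ugt-52 (4.35 ± 0.27) were among those with the smallest p. Camera gave an adjusted p = 2.5e-16 for the cyp list, with an adjusted p = 0.456 with an estimated correlation, and 3.0e-26 for the ugt list, with an adjusted p = 0.145 with an estimated correlation. Fry gave adjusted p = 0.00225 and 4.97e-04. Of 35 glutathione S-transferases 6 rose and 5 fell, with gst-4 at -1.26 ± 0.25 (edgeR adjusted p = 0.0072). Of 30 ABC transporters 8 rose, among them pgp-14 (3.01 ± 0.17), and 3 fell; the 11 calls became 6 without YFP RNAi replicate 1 or 2, and 7 without YFP RNAi with isoflurane replicate 2 or 3. Of 31 fatty acid oxidation genes 8 rose and 2 fell, with daf-22 at 3.30 ± 0.14 (camera adjusted p = 0.00129, with an adjusted p = 0.456 with an estimated correlation; fry 0.00457). The fall of acs-2 (-2.39 ± 0.63, adjusted p = 0.0457) was lost without EV replicate 1 (0.0535), YFP RNAi replicate 1 (0.0640) or 3 (0.156), EV with isoflurane replicate 3 (0.0569), or YFP RNAi with isoflurane replicate 1 (0.147), 2 (0.107) or 3 (0.114). It was lost as well with no filter on low counts (0.131) and without both EV libraries of number 2 (0.0624), with 0.00515 to 0.156 over all alternatives.

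Of 13 metal response genes on YFP RNAi bacteria 7 rose and 1 fell, with cdr-1 at 3.89 ± 0.23 on the log2 scale (camera adjusted p = 7.99e-04, with an adjusted p = 0.681 with an estimated correlation; fry 0.0161). The 8 calls became 4 without YFP RNAi replicate 1 or YFP RNAi with isoflurane replicate 3, and 5 without YFP RNAi replicate 2 or YFP RNAi with isoflurane replicate 2. The gene vit-1 fell by 1.65 ± 0.25, and all 6 vitellogenins lay below 0 (median -0.46, camera adjusted p = 0.0414, with an adjusted p = 0.985 with an estimated correlation; fry 0.545). This camera call ended without YFP RNAi replicate 1 (0.0943) or 2 (0.0989), or YFP RNAi with isoflurane replicate 1 (0.0753) or 3 (0.169). Of 107 collagens 3 fell, with col-98 at -1.89 ± 0.36, and without EV with isoflurane replicate 2 the count was 5. Camera did not pass this list (adjusted p = 0.0598, and 0.0461 with the replicate block). It passed in 8 of 15 alternatives, with adjusted p from 0.00416 to 0.985. Here slo-1 fell by 0.59 ± 0.15 (edgeR adjusted p = 0.0337), the only 1 of 36 anaesthetic sensitivity genes that edgeR called (DESeq2 also 1). It was lost without EV replicate 1 (0.0516), YFP RNAi replicate 1 (0.0812), 2 (0.144) or 3 (0.0728), or YFP RNAi with isoflurane replicate 2 (0.155) or 3 (0.101), and 2 of the list were called without YFP RNAi with isoflurane replicate 1. With no filter on low counts its adjusted p was 0.0568 (0.00409 to 0.155 over all alternatives).

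**Figure D3:**
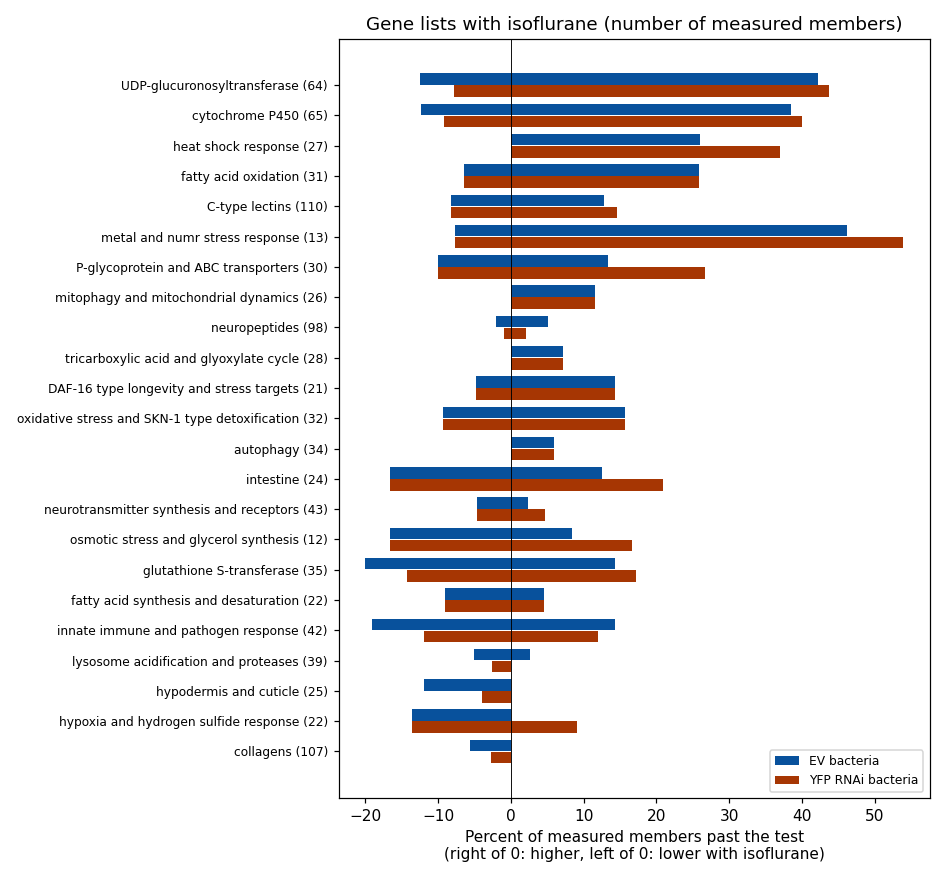
Percent of the measured members of each list (number in brackets) that edgeR called higher (right of 0) or lower (left of 0) with isoflurane, for lists with at least 3 calls summed over both kinds of bacteria. On EV bacteria 27 of 64 UDP-glucuronosyltransferase genes rose and on YFP RNAi bacteria 28 did.

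Isoflurane called largely the same genes on both kinds of bacteria. Of the genes called, 605 rose on both (35.7 expected by chance) and 246 fell on both (7.43 expected), among them cyp-34A10, hsp-70, dct-1 and gpdh-1, and 0 went in opposite directions. The one-sided Fisher exact test gave a -log10 p of 836 for rises and 389 for falls, though genes are not independent replicates. Both sets of calls also rest on the same estimate of the spread, which the numbers expected by chance leave out. On EV bacteria alone 41 rose and 134 fell. Of 220 genes called on YFP RNAi bacteria alone 34 fell and the others rose. Across the 1246 genes called on either, 1244 had the same sign on both, and the log2 fold changes correlated at r = 0.980 (0.908 across all genes).

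**Figure D4:**
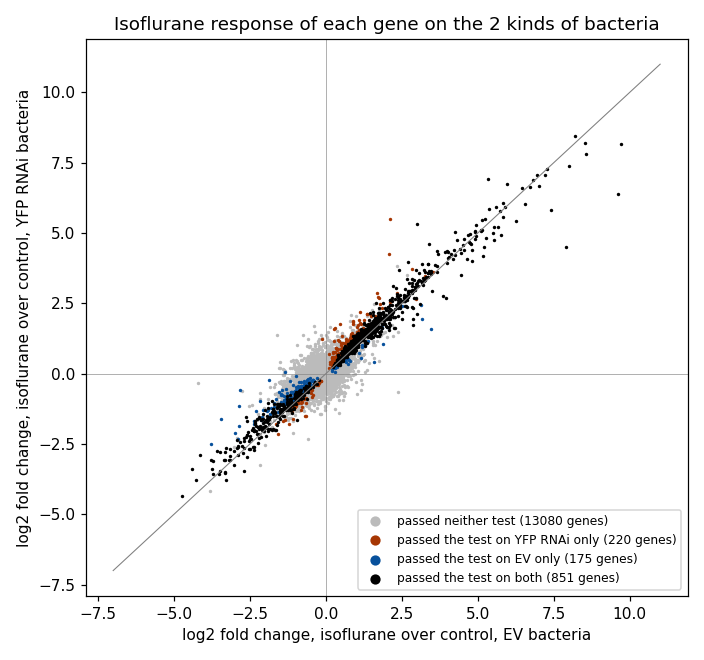
Log2 fold change of each gene with isoflurane on EV bacteria (x) and on YFP RNAi bacteria (y), coloured by the tests it passed; the line marks equal responses. The 851 genes that passed both tests lie in the upper right or lower left.

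The test of the difference itself asked whether the isoflurane response differs between EV and YFP RNAi bacteria. For hsp-70 the difference, EV minus YFP RNAi, was -0.58 ± 0.72 on the log2 scale, for hsp-16.2 -0.41 ± 1.12, for dct-1 -0.03 ± 0.16 and for sqst-1 -0.10 ± 0.25. None of these passed (edgeR adjusted p = 1.00 each). The 5 genes with the smallest p, none of which passed, were F53F1.6 (-1.3 ± 0.38), K10D2.7 (-1.4 ± 0.43), T10B5.2 (-2.98 ± 0.93), C34C6.10 (-1.50 ± 0.49) and K11H3.2 (-1.34 ± 0.46). EdgeR called 0 of 14326 genes, with 89 at an unadjusted p under 0.05, and DESeq2 called 0 (71 unadjusted). These 89 are 0.621% of the genes tested, where no difference at all would give a share near 0.05. The test may thus have been conservative, and the main fit holds no pairing. The cause was not tested. The median SE of a difference was 0.272, and in simulated data the test recovered 11.9% of 1.5-fold, 41.8% of 2-fold and 63.6% of 4-fold differences. The simulated libraries were drawn independently, without the pairing by replicate number.

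Camera passed 8 lists in the test of the difference and fry 0 (lowest adjusted p = 0.597). By camera the difference, EV minus YFP RNAi, lay below 0 for the UDP-glucuronosyltransferases (median -0.26, adjusted p = 3.1e-05, with an adjusted p = 0.681 with an estimated correlation), and for the glutathione S-transferases (-0.27, adjusted p = 6.3e-04, with an adjusted p = 0.985 with an estimated correlation; 0.0726 without EV with isoflurane replicate 1). It lay below 0 as well for 30 ABC transporters (median -0.16, adjusted p = 0.00496), 107 collagens (-0.28, 2.65e-04), 19 pharynx muscle genes (-0.31, 0.00683) and 32 sperm genes (-0.18, 0.0375), each with an adjusted p = 0.985 with an estimated correlation. It lay above 0 for 38 germline genes (median 0.11, adjusted p = 1.46e-06, with an adjusted p = 0.985 with an estimated correlation) and 27 core histones (0.15, adjusted p = 8.83e-04, with an adjusted p = 0.456 with an estimated correlation). No left-out library ended the calls of the ugt genes and histones, while that of the germline genes ended without YFP RNAi with isoflurane replicate 3 (0.675). The ABC transporter call ended without EV with isoflurane replicate 2 (0.889) or YFP RNAi with isoflurane replicate 2 (0.132). That of the collagens ended without EV replicate 2 (0.102), YFP RNAi replicate 2 (0.144) or 3 (0.0618), EV with isoflurane replicate 3 (0.620), or YFP RNAi with isoflurane replicate 1 (0.260) or 3 (0.0855). For the pharynx it ended without EV replicate 2 (0.494), YFP RNAi replicate 1 (0.111), EV with isoflurane replicate 1 (0.159) or YFP RNAi with isoflurane replicate 3 (0.461). For sperm genes it ended without YFP RNAi replicate 2 (0.489) or 3 (0.0796), EV with isoflurane replicate 3 (0.820) or YFP RNAi with isoflurane replicate 1 (0.233), and turned to the other direction without EV replicate 2 (0.785) or EV with isoflurane replicate 1 (0.824). With the replicate block all 8 passed, with adjusted p from 1.99e-06 (germline) to 0.0352 (sperm). The block added body wall muscle genes (0.0172, against 0.102 without it and 2.96e-09 to 0.985 over all alternatives) and vitellogenins (0.00986, against 0.199 without it and 6.15e-04 to 0.985), both below 0. In all 8 lists edgeR called 0 members (2 each of the ugt and gst genes, 1 each of the collagens and pharynx genes and 0 of the others at an unadjusted p under 0.05, DESeq2 0), and it called 0 in the 2 that the block added (0 unadjusted, DESeq2 0).

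Without isoflurane, YFP RNAi against EV bacteria gave no gene past the test. The 5 smallest p were those of the chemoreceptor gene sri-16 (log2 fold change -2.91 ± 0.38, lowest edgeR adjusted p = 0.072), ttr-25 (1.68 ± 0.26), F08G2.8 (-1.50 ± 0.26), F08D12.7 (1.92 ± 0.35) and Y71H2AM.25 (-1.37 ± 0.25). The heat shock gene hsp-70 stood at -0.57 ± 0.53, hsp-16.2 at -0.29 ± 0.85, hsp-6 at -0.06 ± 0.16, hsp-60 at -0.02 ± 0.09, hsp-4 at -0.01 ± 0.15, dct-1 at 0.05 ± 0.12 and sqst-1 at -0.16 ± 0.18. Those of pink-1 (0.02 ± 0.08), pdr-1 (0.04 ± 0.06), lgg-1 (-0.09 ± 0.12), hlh-30 (-0.09 ± 0.13), gas-1 (0.15 ± 0.07), isp-1 (0.08 ± 0.08), sod-3 (-0.31 ± 0.41), gst-4 (0.01 ± 0.24) and acs-2 (-0.11 ± 0.59) did not pass either. EdgeR called 0 of 14326 genes, and 1 without YFP RNAi with isoflurane replicate 1. At an unadjusted p under 0.05 there were 210, which is 1.47% of those tested, where no difference would give a share near 0.05. DESeq2 called 12 (8 up, 4 down). For 645 genes the groups did not overlap, 4.50% against 10% by chance.

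With isoflurane, YFP RNAi against EV bacteria gave 1 gene. The gene sri-16 (WBGene00005528, chromosome I, 12148080 to 12150741, WBcel235) stood at 1.37 ± 0.11 CPM on EV and 0.181 ± 0.087 CPM on YFP RNAi bacteria (SD, n = 3), a log2 fold change of -2.90 ± 0.33 (edgeR adjusted p = 0.0190). Its call ended without EV replicate 1 (adjusted p = 0.0629) or 3 (0.0633), YFP RNAi replicate 2 (0.0609) or 3 (0.0580), EV with isoflurane replicate 1 (0.163) or 3 (0.128), or YFP RNAi with isoflurane replicate 2 (0.131) or 3 (0.134), which left 0 genes. The count was 18 without EV with isoflurane replicate 2. The next smallest p were those of srh-30 (3.33 ± 0.50), F08D12.7 (2.09 ± 0.34), ttr-25 (1.55 ± 0.26) and F35F10.5 (2.58 ± 0.44), which did not pass. Values of hsp-70 (0.01 ± 0.50), hsp-16.2 (0.12 ± 0.73), hsp-6 (-0.15 ± 0.16), hsp-60 (-0.09 ± 0.09), hsp-4 (0.00 ± 0.15), dct-1 (0.08 ± 0.12), sqst-1 (-0.07 ± 0.17), pink-1 (0.04 ± 0.08), pdr-1 (-0.05 ± 0.06), lgg-1 (0.01 ± 0.12), hlh-30 (-0.13 ± 0.13), gas-1 (0.20 ± 0.07), isp-1 (-0.00 ± 0.08), sod-3 (0.21 ± 0.39), gst-4 (0.49 ± 0.26) and acs-2 (0.03 ± 0.63) did not pass. At an unadjusted p under 0.05 there were 445 genes, which is 3.11% of those tested, where no difference would give a share near 0.05. DESeq2 called 15 genes (9 up, 6 down), and edgeR with the replicate block 9 (4 up, 5 down). For 884 genes the groups did not overlap, 6.17% against 10% by chance.

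Body wall muscle, collagen and sperm lists lay above 0 for YFP RNAi against EV bacteria, with 0 members called by edgeR or DESeq2. Of the 45 lists fry passed 0 in either test of YFP RNAi (lowest adjusted p = 0.930 without isoflurane and 0.426 with it), where camera passed 7 and 12. Of 31 body wall muscle genes 28 had log2 fold changes above 0 without isoflurane (median 0.29; 0 at an unadjusted p under 0.05) and 28 with it (median 0.42; 5 unadjusted), with myo-3 at 0.27 ± 0.21 and 0.84 ± 0.21. Their camera adjusted p was 5.3e-08 and 2.9e-11, with an adjusted p = 0.985 with an estimated correlation in both; without EV replicate 3 the first was 0.210. Medians of 107 collagens were 0.38 (1 unadjusted) and 0.66 (12 unadjusted), with camera adjusted p = 1.9e-08 and 3.0e-18, and an adjusted p = 0.985 and 0.681 with an estimated correlation; without YFP RNAi replicate 1 the first was 0.326. Medians of 32 sperm genes were 0.37 and 0.75 (0 unadjusted in both), with camera adjusted p = 1.5e-04 and 3.9e-09, and an adjusted p = 0.985 with an estimated correlation in both. The first call ended without EV replicate 1 (0.158) or YFP RNAi replicate 1 (0.241).

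Other tissue lists differed less evenly, again with 0 members called by edgeR or DESeq2. Of 38 germline genes 33 had log2 fold changes above 0 without isoflurane (median 0.06, camera adjusted p = 0.0375) but 5 with it (median -0.06, adjusted p = 0.00342), with an adjusted p = 0.985 with an estimated correlation in both and 0 genes at an unadjusted p under 0.05. The first call ended without EV replicate 1 (0.629) or 2 (0.0846), YFP RNAi replicate 1 (0.816), EV with isoflurane replicate 1 (0.0635), 2 (0.0549) or 3 (0.0510), or YFP RNAi with isoflurane replicate 2 (0.0709). It ended as well with DESeq2 size factors (0.0532) or the replicate block (0.0719), for a range of 0.0151 to 0.985 over all alternatives. The second ended without EV with isoflurane replicate 3 (0.0628) and turned to the other direction without YFP RNAi with isoflurane replicate 3 (0.397). With isoflurane camera passed for 19 pharynx muscle genes (median 0.37, adjusted p = 1.49e-05, with an adjusted p = 0.811 with an estimated correlation; 2 unadjusted). It also passed for 25 hypodermis and cuticle genes (0.34, adjusted p = 0.00521; 2 unadjusted) and 24 intestine genes (0.12, adjusted p = 0.0286; 3 unadjusted), both with an adjusted p = 0.985 with an estimated correlation. Without isoflurane these 3 lists had adjusted p = 0.148, 0.0586 and 0.670 (0 unadjusted in each). In the test of the difference camera passed the pharynx list (0.985 with an estimated correlation, up to 0.494 without 1 library). It passed neither the hypodermis (adjusted p = 0.332) nor the intestine list (0.123). The calls with isoflurane ended without YFP RNAi with isoflurane replicate 3 (pharynx 0.0507, hypodermis 0.792, intestine 0.467). Those of the last 2 ended without EV with isoflurane replicate 3 as well (0.154 and 0.117), and that of the intestine without EV with isoflurane replicate 1 (0.102) or YFP RNAi with isoflurane replicate 2 (0.130). With the replicate block camera also passed the vitellogenins above 0 with isoflurane (2.96e-04, against 0.0622 without the block and up to 0.985 over all alternatives). Without isoflurane it passed 42 innate immune genes below 0 (0.0255, against 0.0622 and 4.53e-04 to 0.989).

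Other lists that camera passed for YFP RNAi also had 0 members called by edgeR or DESeq2, with an adjusted p = 0.985 with an estimated correlation unless given. Without isoflurane they were 28 genes of the tricarboxylic acid cycle (median log2 fold change 0.05, camera adjusted p = 0.0120; 1 unadjusted), 81 cytosolic ribosomal proteins (-0.06, 6.34e-04; 0 unadjusted) and 36 anaesthetic sensitivity genes (0.03, 0.0198; 1 unadjusted). The first call ended without EV replicate 2 (0.0540) or 3 (0.139), or YFP RNAi replicate 1 (0.222) or 2 (0.0694). That of the ribosomal proteins ended without YFP RNAi replicate 2 (0.0880) and turned to the other direction without EV replicate 1 (0.0136). The anaesthetic sensitivity call ended without EV replicate 3 (0.856), or YFP RNAi replicate 1 (0.0934) or 2 (0.321). With isoflurane, 34 autophagy genes lay below 0 (median -0.06, adjusted p = 0.0106, with an adjusted p = 0.471 with an estimated correlation; 1 unadjusted), as did 27 core histones (-0.15, adjusted p = 9.32e-04, with an adjusted p = 0.456 with an estimated correlation; 3 unadjusted). Above 0 lay 64 ugt genes (0.19, adjusted p = 1.54e-04, with an adjusted p = 0.811 with an estimated correlation; 3 unadjusted), 35 gst genes (0.20, 9.32e-04; 2 unadjusted) and the anaesthetic sensitivity genes (0.11, 0.0355; 1 unadjusted). Without EV with isoflurane replicate 1 the calls of autophagy (0.203) and gst genes (0.102) ended, and without its replicate 2 those of histones (0.0618), ugt (0.0768) and anaesthetic sensitivity genes (0.177). Its replicate 3 ended those of gst (0.0510) and anaesthetic sensitivity genes (0.195). Without YFP RNAi with isoflurane replicate 3 autophagy (0.228), ugt (0.0637) and gst genes (0.0556) did not pass. The anaesthetic sensitivity call also ended without YFP RNAi with isoflurane replicate 1 (0.308) or 2 (0.186), and with the replicate block (0.0507; 0.00483 to 0.985 over all alternatives).

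Between libraries of 1 kind muscle markers varied as much: the mean log2 CPM of the muscle genes, relative to all 12 libraries, was 0.39 in EV replicate 2 against -0.30 and -0.59 in EV replicates 1 and 3. With isoflurane it was 0.31 in EV replicate 2 against -0.41 and -0.50. Without both EV libraries of number 2, an alternative chosen after seeing the data from these very markers, 23 genes were called without isoflurane (18 up) and 113 with it (98 up).

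**Figure D5:**
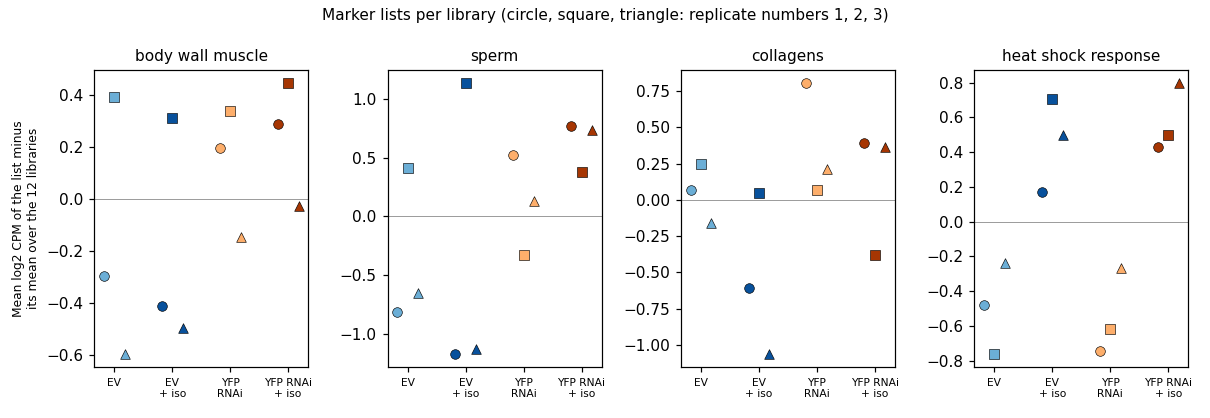
Mean log2 CPM of 4 gene lists per library, minus the mean over the 12 libraries, by group, with shape for the replicate number. Body wall muscle scores were 0.39 and 0.31 in the EV libraries of number 2 and below 0 in the other EV libraries; heat shock scores were above 0 in all 6 isoflurane libraries and below 0 in all 6 controls.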

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

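Leaving out both EV libraries of number 2 was chosen only after the result was seen, from their muscle and sperm RNA; the other tests here were planned. The 1026 genes of isoflurane on EV bacteria stayed within 1.5 times under 7 alternatives (703 with the 2-fold threshold, 1389 with the replicate block), and at 797 to 1083 without 1 library. On YFP RNAi bacteria the 1071 became 757 to 1470, and 759 to 1146 without 1 library. The overlap of 851 became 805 to 1131. The interaction stayed at 0 by edgeR and DESeq2 in every setting run (71 to 321 at an unadjusted p under 0.05). No setting blocked by number within each kind of bacteria.

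YFP RNAi without isoflurane, at 0 by edgeR (210 unadjusted), had 1 gene with the replicate block, 12 by DESeq2, 23 without both EV libraries of number 2, and 0 to 1 without 1 library (1 without YFP RNAi with isoflurane replicate 1). With isoflurane, the 1 gene became 9 with the block, 15 by DESeq2, 113 without both EV libraries of number 2, 0 by edgeR with only the 6 libraries compared (308 unadjusted), and 0 to 18 without 1 library (18 without EV with isoflurane replicate 2). A rise of muscle and sperm genes there follows from how these libraries were picked; otherwise the cause was not tested.

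Of 225 list tests camera passed 43, and 0 with an estimated correlation (15 unadjusted); the estimated correlations of the 43 were 0.0163 to 0.831 (preset 0.01), and the cause was not tested; without 1 library 43 to 67 passed (67 without EV with isoflurane replicate 2). Leaving out 1 library reversed 3 list tests. Adjusted p ranged from 6.5e-12 to 0.0880 for ribosomal proteins with YFP RNAi without isoflurane (reversed without EV replicate 1, 0.0136) and from 2.3e-06 to 0.397 for germline genes with isoflurane. It ranged from 2.1e-28 to 0.824 for sperm genes in the interaction (reversed without EV replicate 2, 0.785, or EV with isoflurane replicate 1, 0.824). The cause was not tested. Of 88 named genes called on EV bacteria 74 stayed called in every setting, and of 90 on YFP RNAi bacteria 75. Thinning all libraries to 21831518 reads gave 998 and 1022 calls of isoflurane in place of 1026 and 1071. The filter on low counts left 14326 genes, and 21037 were tested without it.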

Other observations

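The tests of near-identical copies, polyglutamine load, pairs of libraries, and the splits for YFP RNAi and the interaction were chosen only after the result was seen. Defence and metabolic genes not described above also changed with isoflurane, on EV and then YFP RNAi bacteria. Among innate immune genes, irg-6 rose by 4.12 ± 0.43 and 4.26 ± 0.43 on the log2 scale and the lysozyme gene lys-1 fell by 0.83 ± 0.10 and 0.59 ± 0.10. The C-type lectin clec-57 rose by 2.39 ± 0.18 and 2.55 ± 0.18, and clec-49 fell by 2.50 ± 0.18 and 2.23 ± 0.17. The cytosolic aconitase aco-1 rose by 1.56 ± 0.11 and 1.67 ± 0.11, and idh-1 by 0.63 ± 0.10 and 0.58 ± 0.10. The pyruvate kinase pyk-2 fell by 1.45 ± 0.16 and 1.12 ± 0.16, the lipid regulator sbp-1 by 0.86 ± 0.12 and 0.74 ± 0.12, and the glutamate-gated chloride channel avr-15 by 1.68 ± 0.19 and 1.37 ± 0.19.

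Of 7 heat shock genes called on both kinds of bacteria (hsp-16.2, hsp-16.11, hsp-16.41, hsp-70, F44E5.4, hsp-17 and sti-1), 7 stayed called on both after all libraries were thinned to 21831518 reads, which argues against library depth. Outside near-identical copies 3 were called on both (hsp-70, hsp-17 and sti-1). The rise was thus not limited to these copies. Reads shared between copies would still follow a rise of any 1 of them, so these calls cannot tell whether reads were shared. Whether each of the hsp-16 genes and F44E5.4 rose by itself stays open. Without EV replicate 2 (hsp-17 0.0872, sti-1 0.0722 on EV bacteria) or YFP RNAi replicate 2 (hsp-17 0.0538, sti-1 0.0927 on YFP RNAi bacteria), of the members outside such copies only hsp-70 was called on both. The log2 fold changes of hsp-17, 2.05 ± 0.47 and 2.36 ± 0.47 (SE) on EV and YFP RNAi bacteria, stayed above 0 without any 1 library (1.79 to 2.48 and 2.02 to 3.01). So did those of sti-1, 0.38 ± 0.08 and 0.35 ± 0.08 (0.26 to 0.44 and 0.34 to 0.37). Calls of 1 of the 2 ended without EV replicate 1 (hsp-17 0.0949) or 3 (sti-1 0.0542), or EV with isoflurane replicate 2 (hsp-17 0.0613) or 3 (hsp-17 0.0527), and with no filter on low counts (hsp-17 0.0803). That of sti-1 ended without YFP RNAi replicate 1 (0.0787) or 3 (0.0764), or YFP RNAi with isoflurane replicate 1 (0.0626) or 2 (0.0679). For heat shock genes called in these same data, the median log2 response was 2.11 ± 1.1 on EV bacteria (SD, n = 3 replicate numbers). On YFP RNAi bacteria it was 2.66 ± 0.45. Matched by number, the median difference, EV minus YFP RNAi, was -0.54 ± 1.24 (-1.77, 0.71 and -0.55). The numbers were not taken to pair EV with YFP RNAi libraries without isoflurane, so these signs and this SD depend on the matching. The SD on EV bacteria alone exceeds the mean difference, so an effect of polyglutamine load, which was not measured here, stays open. So does handling or warming during the exposure, which no group separates from isoflurane.

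Between the tests without and with isoflurane, 107 genes had an unadjusted p under 0.05 for YFP RNAi in both and the same sign (77 up, 30 down), of 108 in both tests against 6.52 expected if the tests were unrelated. Over all genes the log2 fold changes of the tests had r = 0.447. The 2 libraries with the same bacteria and replicate number were then combined as if from 1 culture, an assumption from the pattern of the data that the labels do not state. Of the splits of these 6 pairs, 10 of 10 had at least as many genes at an unadjusted p under 0.05 as the real one, which had 290 (312 to 2289 in the others). EdgeR called 0 genes in the real split and 44 in the split that sets EV 1, EV 3 and YFP RNAi 3 against the rest. The other splits that part EV from YFP RNAi at every replicate number, as the real one does, had 312, 423 and 678 genes. The rest set both pairs of 1 number on the same side. A difference between numbers shared by both bacteria could raise their counts, so the 10 of 10 rests in part on this layout. Differences between such pairs could give the recurrence, and an effect of YFP RNAi is not excluded. Of the 107 genes 72.0% had an average of at least 1 log2 CPM against 73.8% of all tested, so they held no marked excess of low counts. The share fell between the 2 bounds set before the test. The upper bound lies above the share of all genes tested, so these bounds cannot decide on low counts.

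Sperm gene RNA differed between these pairs of libraries within 1 kind of bacteria. Moulting genes (17, of which 2 are also in the hypodermis list; noah-1 highest at 89.6 CPM) did not rise with sperm genes (spe-15 highest at 11 CPM) over the 6 pairs: r = -0.54 (exact p = 0.257, adjusted p = 0.257 over 4 relations; -0.31 without the 2 farthest pairs). This r lay under the bound of 0.3 set for it before the test. Its 95% interval, -0.94 to 0.48, which that bound did not ask for, reaches above 0.3. The moulting genes also have a median of 3.09 log2 CPM against -1.02 for the sperm genes, a baseline that would hide a small share of larvae, so larvae in the pools stay open. Scores of msp and other sperm genes had r = 0.998 (exact p = 0.00139, the smallest that 720 permutations can give, adjusted p = 0.00556). The difference was thus not limited to msp genes. Reads shared between msp copies would still follow total msp RNA, so this r cannot tell whether reads were shared. Sperm genes had r = 0.860 with collagens (adjusted p = 0.05) and 0.819 with muscle genes (adjusted p = 0.0815; -0.10 without the 2 farthest pairs). No biological explanation was tested.

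With 10 splits of 6 libraries, splits are too few for a share under 0.05. Isoflurane on EV bacteria called 1026 genes, in 1 of 10 splits, with a highest other of 0, also among the 3 other splits that part 3 pairs. On YFP RNAi bacteria it called 1071, in 1 of 10, with a highest other of 54 in a split that parts 1 pair, and 0 among the 3 that part 3 pairs. YFP RNAi without isoflurane called 0 genes by edgeR (DESeq2 12), a count that any split meets, so 10 of 10 (highest other 1) says nothing about chance. With isoflurane it called 1, in 1 of 10 (highest other 0). Other splits there had up to 1921 and 1699 genes at an unadjusted p under 0.05 against 210 and 445 in the real ones, which points to a structure of the samples. For the interaction, edgeR called 0 genes (89 unadjusted, DESeq2 0), so 100 of 100 splits (highest other 17) says nothing about chance either.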
